A study of Mus musculus with 12 samples.

How the data were processed

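RNA from brown adipose tissue of 12 adult male ob/ob mice was measured on 12 one-colour Affymetrix arrays, 1 array per mouse, with biotin as the label. Per the labels, 6 mice received an agonistic antibody against FGFR1 and 6 pair-fed mice received a control IgG. The labels state 6 mice in each group, so each replicate is a separate animal.

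The deposited table holds log2 expression values, 1 per probe set and array, for 45101 probe sets. Per the submitters' processing notes, RMA and limma were used, with no version stated. RMA is a method that corrects background, normalizes the arrays against each other and summarises the probes of each probe set on the log2 scale. The values ran from 3.16 to 14.9, with array medians between 7.19 and 7.23, and no detection call or filter is recorded. The values were used as deposited, since normalizing such a table again is itself a choice, and a second quantile normalization was run as an alternative. The background correction and the summary over probes pull small changes of dim probe sets toward 0, so fold changes of dim genes are likely to be understated. Arrays give no counts, and the number of arrays limits the precision.

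Probe sets were named through the platform's probe table, which lists 35890 of them, and symbols were updated through the Entrez identifier to a reference gene table of the mouse assembly GRCm38.p6, in which the identifiers of 34741 probe sets with a single gene were found. A single gene was given for 34945 probe sets and several genes for 932, while 9211 had no entry in the probe table. The 64 control probe sets, and probe sets with several genes or none, stayed out of the gene tests. For each gene the probe set with the highest mean over all 12 arrays was kept, without regard to group, which left 18193 genes. Where probe sets of a gene named by the rule below differed in sign, the text says so. No source used here names a genome build for the values, so no coordinates are given.

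Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates), and tables were read with the data.table package, version 1.17.8. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Log2 fold changes are anti-FGFR1 minus control IgG and are given with the moderated standard error (SE). The shift of 29 gene lists, 18 pathway lists and 11 lists of cell type markers, was tested with limma's camera at a preset correlation between genes of 0.01, again with Benjamini-Hochberg adjustment over the lists. The lists held 593 different genes, of which 551 were measured. The pathway lists were brown fat and thermogenesis, FGF and ERK feedback, FGF ligands, receptors and adaptors, mitochondrial fatty acid oxidation, oxidative phosphorylation, TCA cycle and pyruvate entry, glucose uptake and glycolysis, fatty acid synthesis, triglyceride storage and lipolysis, cholesterol synthesis, unfolded protein and amino acid response, cell cycle, extracellular matrix, interferon response, inflammatory cytokines and acute phase, circadian clock, glucocorticoid response and secreted adipocyte factors. The marker lists were white fat, skeletal muscle, macrophage, T cell, B cell, granulocyte and mast cell, endothelium, smooth muscle and pericyte, fibroblast and preadipocyte, nerve and Schwann cell, and red blood cell. Called members were counted over all genes tested and adjusted over the list alone. Values per array, such as the mean of a list, were compared with a two-sided exact permutation test over all 924 assignments of the arrays to groups, whose smallest possible p is 0.0022.

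Named genes follow a rule. It takes the 10 largest rises and the 10 largest falls among the called genes, the 12 genes Fgfr1, Klb, Fgf21, Ucp1, Ppargc1a, Dio2, Cidea, Lep, Adipoq, Spry4, Dusp6 and Egr1 whatever their values, and up to 3 members of each list with the smallest p. The rule gave 107 genes. Lists, rule, the gene and list tests and most alternatives were fixed before the data were examined. Genes outside the rule are said to be so where they are named.

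The gene test was run on simulated data with 18193 genes of the same means and spread. For the comparison of anti-FGFR1 with control IgG it recovered 28.4% of genes changed by 0.25 on the log2 scale, 89.6% of those changed by 0.5 and 98.5% of those changed by 1, with 5.88% false calls. In the list test a list of 20 genes shifted by 0.25 was called, and of the unshifted lists camera called 0. The simulated genes were independent, whereas the estimated correlation within real lists reached 0.94 (skeletal muscle). The list simulation therefore does not show how often camera falsely calls lists whose genes move together. In the gene simulation, changes of 0.25 were often missed with 6 arrays per group. It gave 153 calls against 1461 in the real data, so its recovery need not equal that of the real test.

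The alternatives were another quantile normalization, centring each array on its median, the replicate number as a block, the mean of all probe sets of a gene, a filter on dim genes, a trended robust prior, array quality weights, the skeletal muscle marker mean or the 3' to 5' ratio of control probe sets as a covariate, leaving out each array in turn, other thresholds, all probe sets, and other settings of the list test. The 3' to 5' ratio is the mean log2 ratio of the 3' to the 5' control probe sets of Gapdh and Actb, a sign of RNA quality. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.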

Results

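Gene expression was measured in brown adipose tissue, the heat-producing fat, of leptin-deficient obese ob/ob mice. The animals were males aged 3 months. Treated mice received 1 dose of 1 mg/kg, into the abdominal cavity, of an antibody that activates the receptor FGFR1, controls were pair-fed and received a control IgG, and the tissue was taken on day 4. Pair-feeding matches the food intake of the control group to that of the treated group. There were 6 arrays in each group, and the values are log2 expression as deposited. Arrays of a group resembled each other closely, with a mean correlation to their own group across probe sets between 0.993 and 0.996. No array shared more than 0.0665% of its values with another, so none was deposited in duplicate.

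The comparison asks which genes respond in brown fat when FGFR1 is activated. Of 18193 genes tested, 1461 changed (limma), 535 of them higher and 926 lower after anti-FGFR1. Most changes were small: the median absolute log2 fold change of the called genes was 0.28, and only 5 genes rose and 4 fell by 1 or more. Normalizing the deposited values once more gave a different balance, with 732 genes higher and 760 lower, so 63.4% of called genes were lower as deposited and 50.9% after the second normalization. No source used here says which arrays were normalized together, so this balance depends on the deposited scale. With the 3' to 5' ratio as a covariate 688 genes were called, 618 of them shared with the 1461. Of the named genes that had passed, 23 lost their call with this covariate; they kept a median of 89.5% of their fold (65.2% to 128%), while their SE grew by a median of 1.29 times, and 6 of them had a larger fold with it.

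The gene with the largest rise was Lcn2, which encodes lipocalin 2, a secreted acute-phase protein. It went from 8.14 ± 0.36 to 9.85 ± 0.37 (SD, n = 6 per group), a 3.27-fold rise with a log2 fold change of 1.71 ± 0.18 (SE, limma adjusted p = 8.7e-05). Sgk2, a serine/threonine kinase, rose by 1.22 ± 0.12, and Pon1, which encodes the esterase paraoxonase 1, by 1.21 ± 0.17. The matrix genes Smoc2, Adamts12 and Col15a1 rose by 1.20 ± 0.08, 1.12 ± 0.14 and 1.00 ± 0.17. The other large rises were those of Ms4a4d (0.92), the clock output gene Dbp (0.90), Scara3 (0.87) and Apod, encoding apolipoprotein D (0.87). In each of these 10 genes all 6 anti-FGFR1 arrays lay above the highest control array. Their limma adjusted p values were between 3.0e-06 (Smoc2) and 0.0025 (Col15a1).

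Inmt, which encodes an enzyme that methylates indoleamines such as tryptamine, showed the largest fall. It went from 10.2 ± 0.12 to 8.30 ± 0.22 (SD, n = 6 per group), 3.72-fold lower, with a log2 fold change of -1.89 ± 0.09 (SE, limma adjusted p = 8.4e-08). Cryab, a small heat shock protein, changed by -1.22 ± 0.26 with 4 of 6 anti-FGFR1 arrays below all controls (limma adjusted p = 0.0098), and with the 3' to 5' ratio as a covariate its call was lost (-1.10 ± 0.34). Within each group, Cryab was lowest on the array lowest in skeletal muscle markers, control IgG replicate 6 (10.9) and anti-FGFR1 replicate 5 (9.54). The same held for Retreg1, a receptor for autophagy of the endoplasmic reticulum (10.8 and 9.46). Both genes kept their calls with the skeletal muscle mean as a covariate. Retreg1 changed by -1.03 ± 0.18. Cpne9 (-0.96), Eya2 (-0.94), Cilp (-0.93), Lox (-0.93), which cross-links collagen, Id4 (-0.93) and Fads3 (-0.92) fell by similar amounts, each with all 6 anti-FGFR1 arrays below all controls. Fdft1, squalene synthase, changed by -1.01 ± 0.13 on the probe set used, but its probe sets disagreed: 2 of the 4 fell and the other 2, which were dimmer, differed by 0.02 and 0.03 and did not pass.

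**Figure D1:**
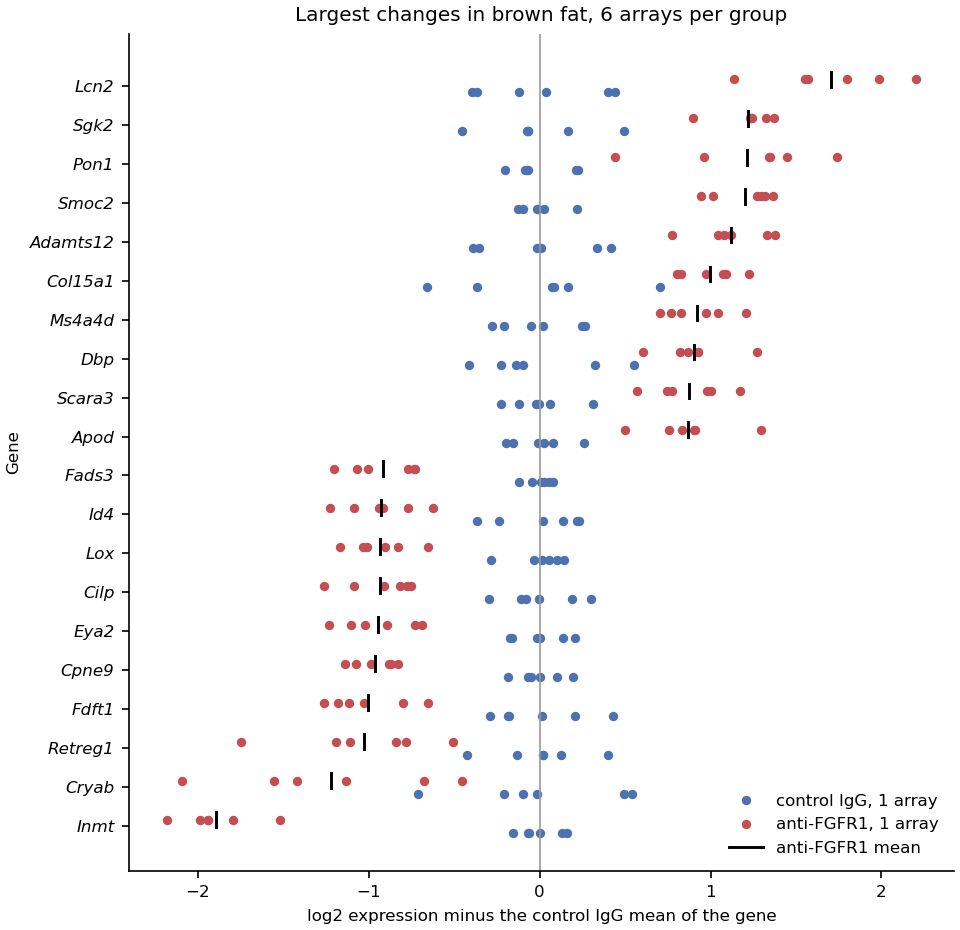
Log2 expression of the 10 genes with the largest rise and the 10 with the largest fall, each relative to its control IgG mean (x axis, log2 units), with 1 point per array and a bar at the anti-FGFR1 mean. Only Cryab, whose fall of 1.22 was the most variable, has anti-FGFR1 arrays within the control range.

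The FGF and ERK feedback list holds genes induced by ERK signalling, the kinase pathway downstream of FGF receptors, and inhibitors that dampen it. Of 28 measured members, 4 rose and 1 fell, and 23 did not pass (adjusted over the list alone, 5 rose and 1 fell). The phosphatase Dusp6 rose by 0.63 ± 0.12 (limma adjusted p = 0.0038) and the inhibitor Spry4 by 0.57 ± 0.10 (limma adjusted p = 0.0024), each above all controls on all 6 arrays. The 2 other rises, named after their values were seen, were Dusp4 (0.79) and Spred2 (0.32). Ccnd1, cyclin D1, fell by 0.90 ± 0.11 on the log2 scale (limma adjusted p = 0.00029). The immediate early gene Egr1 differed by -0.02 ± 0.46 and varied widely among controls (SD 1.19). The list as a whole did not pass camera (limma adjusted p = 0.162), although it did with the 3' to 5' covariate (0.0129) and without control IgG replicate 6 (0.0484). With the macrophage mean as a covariate its direction turned (limma adjusted p = 0.969), and 4 members rose and 4 fell.

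Among 22 FGF ligands, receptors and adaptors, 0 rose and 2 fell by limma, with 5 at an unadjusted p under 0.05, and the list did not pass camera (limma adjusted p = 0.241). Fgf1 fell by 0.52 ± 0.07 on the log2 scale (limma adjusted p = 0.00044), and Fgf18 by 0.23 ± 0.06 (limma adjusted p = 0.040). The call of Fgf18 was lost when any of 10 of the 12 arrays was left out. Fgfr1 itself, the antibody's target, differed by -0.20 ± 0.09 and did not pass (limma adjusted p = 0.197); 1 of its 3 probe sets was at 0.03. With the macrophage mean as a covariate Fgfr1 was at -0.30 and passed (limma adjusted p = 0.0391). Without a covariate, no call was made for Klb, the co-receptor beta-Klotho (-0.04 ± 0.06, and 0.15 on its dimmer probe set), Fgf21 (0.09 ± 0.11) or Kl (0.15 ± 0.06). Kl passed with the macrophage mean as a covariate (0.20, limma adjusted p = 0.0486).

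The brown fat programme did not move in one direction. Ucp1, the uncoupling protein that makes heat, differed by 0.03 ± 0.04 at a control level of 14.5, where only 2 genes were brighter on average, so it sat near the top of the array's range. Cidea (-0.03 ± 0.04) and Dio2 (0.12 ± 0.14, against -0.25 and -0.14 on its other probe sets) did not pass either. Cidea was also near the top of the range, with 13 genes brighter on average. Of 24 measured members of the list, 4 rose and 5 fell, and camera gave a limma adjusted p of 0.759. Letmd1, a mitochondrial protein of brown fat, rose by 0.29 ± 0.04, while P2rx5, an ATP receptor and brown adipocyte marker, and Ucp3 fell by 0.52 ± 0.06 and 0.46 ± 0.10 on the log2 scale, the call of Ucp3 being lost with the 3' to 5' covariate (-0.39 ± 0.13). Elovl3, a fatty acid elongase, rose by 0.76 and Ppargc1b by 0.26, both named after their values were seen. Ppargc1a, the coactivator that drives mitochondrial biogenesis, differed by 0.26 ± 0.09 on the probe set used (limma adjusted p = 0.115), whereas 3 of its 5 probe sets rose, by 0.43, 0.51 and 0.43, and the other 2 were 0.23 and 0.26. With the 3' to 5' covariate 2 members of the list rose and 1 fell.

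Among the mitochondrial and carbohydrate lists, 2 passed camera at the preset correlation with small medians, and oxidative phosphorylation and glycolysis did not pass. In the list of TCA cycle and pyruvate entry, 20 of 22 members had a fold change above 0, with a median of 0.06, and the list passed camera (limma adjusted p = 0.0027) but not with an estimated correlation (adjusted p = 0.573). Its mean per array was 0.068 higher after anti-FGFR1 (exact permutation p = 0.0043), with 5 of 6 anti-FGFR1 arrays above all controls. Pdhb, a subunit of pyruvate dehydrogenase, was the only member that passed (0.16 ± 0.05). Its call was lost when any of 10 arrays was left out, and with the 3' to 5' covariate (0.14 ± 0.06, limma adjusted p = 0.253). Pdk2 and Suclg2 differed by 0.20 and 0.18 and did not pass. Mitochondrial fatty acid oxidation had 17 of 20 members above 0 (median 0.05, limma adjusted p = 0.0185, and 0.573 with an estimated correlation), and its call was lost without control IgG replicate 1 (0.0989), anti-FGFR1 replicate 3 (0.0627) or anti-FGFR1 replicate 4 (0.0507). Cpt2, carnitine palmitoyltransferase 2, rose by 0.22 ± 0.05, a call lost with the mean of its probe sets (0.24, limma adjusted p = 0.159), and Echs1 (0.14) and Etfb (0.10) did not pass. Oxidative phosphorylation did not pass camera (limma adjusted p = 0.257). Of its 44 members only Uqcrc2 rose (0.18 ± 0.05), and Ndufb5 (0.10) and Atp5g3 (-0.09) did not pass. The call of Uqcrc2 was lost when any of 11 arrays was left out, and with the 3' to 5' covariate (0.16 ± 0.07, limma adjusted p = 0.249). In glucose uptake and glycolysis (limma adjusted p = 0.234), Pgam1 and Pfkl rose by 0.20 and 0.21 and 18 of 20 members did not pass, among them Hk1 (0.26). Both calls were lost with the 3' to 5' covariate, at slightly larger values with a larger error (0.21 ± 0.06 and 0.23 ± 0.06).

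Lipid genes changed in both directions. Of 19 genes of fatty acid synthesis, the desaturase Scd2 rose by 0.78 ± 0.13 and Pgd by 0.28 ± 0.05, while Pnpla3 (-0.36) did not pass, and the list did not shift (limma adjusted p = 0.304). Of 25 genes of triglyceride storage and lipolysis, 1 rose and 3 fell (limma adjusted p = 0.759). Angptl4, an inhibitor of lipoprotein lipase, fell by 0.47 ± 0.06 on the log2 scale, and Gpihbp1, which carries that lipase across the capillary wall, by 0.19 ± 0.04. Gpd1 rose by 0.24 ± 0.05, a call lost with the mean of its probe sets (0.15, limma adjusted p = 0.0658). With the 3' to 5' covariate, the calls of Gpd1 (0.23 ± 0.07) and Gpihbp1 (-0.18 ± 0.06) were lost. Of 20 genes of cholesterol synthesis, Insig1 (0.44 ± 0.07) and Nsdhl (0.25 ± 0.07) rose and Fdft1 fell, and the list did not pass (limma adjusted p = 0.304). The call of Nsdhl was lost when any of 6 arrays was left out, and with the 3' to 5' covariate (0.31 ± 0.09).

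Leptin and resistin, hormones made by fat cells, moved in opposite directions. Lep transcript fell by 0.56 ± 0.10 on the log2 scale (limma adjusted p = 0.0040) and Retn rose by 0.69 ± 0.08 (limma adjusted p = 0.00023), each separating the groups on all 6 arrays. The ob/ob mutation leaves a Lep transcript without a working hormone. Fst, follistatin, fell by 0.69 ± 0.10 on the log2 scale. Adipoq, adiponectin, differed by 0.08 ± 0.05 and did not pass (limma adjusted p = 0.294), with only 23 genes brighter on average. Of 20 secreted adipocyte factors, 1 rose and 4 fell (limma adjusted p = 0.304 for the list), and of 15 white fat markers, 3 rose and 2 fell (limma adjusted p = 0.304), among them Npr3 (-0.31 ± 0.07), whose call was lost with the 3' to 5' covariate (-0.22 ± 0.08).

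Markers of blood vessels were lower as lists, though not every marker fell. Of 14 endothelial markers, 7 fell and 0 rose (11 fell adjusted over the list alone), with a median log2 fold change of -0.26. The adhesion molecule Pecam1 fell by 0.52 ± 0.06 on the log2 scale, Plvap by 0.37 ± 0.07 and Robo4 by 0.29 ± 0.06. Among those that did not pass, Kdr (0.02), Vwf (-0.05) and Flt1 (-0.06) hardly differed. Of 10 markers of smooth muscle and pericytes, 6 fell, with a median of -0.27. Tagln fell by 0.64 ± 0.08, Acta2, smooth muscle actin, by 0.57 ± 0.05 and Myh11, smooth muscle myosin, by 0.52 ± 0.05. Pdgfrb (0.0086) and Mylk (0.03) did not pass. With the mean of their probe sets, Acta2 was at -0.34 and Myh11 at -0.28, both still called. The mean of the endothelial markers went from 9.64 ± 0.07 to 9.40 ± 0.09, and that of the smooth muscle and pericyte markers from 10.04 ± 0.07 to 9.74 ± 0.08 (SD, n = 6 per group), with an exact permutation p of 0.0022 each, the smallest the design allows. Camera gave limma adjusted p values of 3.7e-07 and 8.4e-07, but 0.286 and 0.233 with an estimated correlation. Fry, which asks whether a list's genes move one way on balance, gave 0.0074 and 0.00021. The 3' to 5' ratio also differed between the groups, at 0.161 ± 0.031 in controls and 0.203 ± 0.027 after anti-FGFR1 (SD, n = 6 per group, exact permutation p = 0.0368). The part from Actb differed by 0.0692 (exact permutation p = 0.0433) and that from Gapdh by 0.0142 (exact permutation p = 0.506). With the ratio as a covariate, both lists still passed camera, and 1 endothelial marker, Pecam1, and 5 markers of smooth muscle and pericytes remained called. The 6 endothelial markers that lost their call were then at -0.35 (Plvap), -0.35 (Tek), -0.30 (Esam), -0.26 (Robo4), -0.27 (Tie1) and -0.18 (Egfl7), against -0.37, -0.34, -0.29, -0.29, -0.35 and -0.27 without it. Tek, Esam, Tie1, Egfl7, Kdr, Vwf, Flt1, Pdgfrb and Mylk are named after their values were seen.

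Markers of several immune cells were higher, though the T cell, B cell, and granulocyte and mast cell lists were dim. Their control means were 6.58, 6.64 and 7.01, against array medians between 7.19 and 7.23. Of 18 macrophage markers, 3 rose: Adgre1, which encodes the antigen F4/80, by 0.63 ± 0.15, Cd5l by 0.60 ± 0.09 and the growth factor receptor Csf1r by 0.37 ± 0.10. The call of Adgre1 was lost with the 3' to 5' covariate, where its fold was larger (0.75 ± 0.20, limma adjusted p = 0.0509), and that of Csf1r when any of 8 arrays was left out. The macrophage list passed camera (limma adjusted p = 0.0016, and 0.573 with an estimated correlation), whereas its mean per array did not separate the groups (difference 0.22, exact permutation p = 0.121). The difference of that mean passed the test without control IgG replicate 6 (0.308, exact permutation p = 0.0173). It also passed without the 2 arrays lowest in muscle markers (0.286, exact permutation p = 0.0317). In both cases the groups still overlapped. Of 11 granulocyte and mast cell markers, the mast cell proteases Cma1 (0.29 ± 0.06) and Cpa3 (0.39 ± 0.10) rose, S100a9 (0.20) did not pass, and all 11 were above 0 (limma adjusted p = 0.0016, and 0.286 with an estimated correlation). Both calls were lost with the 3' to 5' covariate (0.22 ± 0.07 and 0.33 ± 0.13), which also ended that of the list (0.0880). The mean per array of this list was 0.15 higher after anti-FGFR1 (exact permutation p = 0.0065), with 4 of 6 anti-FGFR1 arrays above all controls. Ms4a1, a B cell antigen, rose by 0.22 ± 0.05 and the immunoglobulin heavy chain gene Ighm by 0.68 ± 0.18, though the dimmer probe set of Ms4a1 was at -0.01, and of the 11 probe sets of Ighm 2 passed and 2 lay below 0. The call of Ms4a1 was lost with the mean of its probe sets (0.11, limma adjusted p = 0.113) and with the 3' to 5' covariate (0.14 ± 0.05). That of Ighm was lost when any of 6 arrays was left out, and with the 3' to 5' covariate (0.87 ± 0.23, limma adjusted p = 0.0514). Pou2af1 (0.19) did not pass, and the 11 B cell markers passed camera as a list (limma adjusted p = 0.0173, and 0.573 with an estimated correlation, 0.200 with the 3' to 5' covariate, 0.0587 after another quantile normalization). Of 12 T cell markers 0 passed limma, with 3 at an unadjusted p under 0.05: Cd8b1 (0.14), Ccr7 (0.18) and Cd4 (0.13). The T cell list passed camera (limma adjusted p = 0.0365, and 0.573 with an estimated correlation), but not without control IgG replicate 3 (0.0585), control IgG replicate 4 (0.0730) or anti-FGFR1 replicate 2 (0.0694). Its call was also lost with the 3' to 5' covariate (limma adjusted p = 0.447) and after another quantile normalization (0.0838).

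Cell cycle genes were higher as a list, with 30 of 32 above 0 and a median of 0.28 (limma adjusted p = 6.7e-06, and 0.573 with an estimated correlation). The mitotic kinesin Kif20a was the only one that rose by itself (0.49 ± 0.11, and 5 rose adjusted over the list alone). Kif11 (0.39) and Prc1 (0.36) did not pass. With the 3' to 5' covariate 4 members rose, among them Kif11 (0.56, limma adjusted p = 0.0370) and Prc1 (0.53, limma adjusted p = 0.0453). The mean of the list went from 7.68 ± 0.28 to 7.95 ± 0.23 (SD, n = 6 per group, exact permutation p = 0.0974). Without control IgG replicate 6 the difference was 0.352 (exact permutation p = 0.0303), and without the 2 arrays lowest in muscle markers 0.348 (exact permutation p = 0.0476). Across the 12 arrays, with each array taken relative to its group mean, the mean of this list followed that of the macrophage markers (Pearson r = 0.887, permutation p = 0.00016, adjusted 0.00024; Spearman rho = 0.951, p = 9e-05, adjusted 0.00014), and without the 2 farthest arrays r was 0.843. With the macrophage mean as a covariate, the cell cycle list no longer passed camera (0.306).

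Among 31 genes of the extracellular matrix, 9 rose and 2 fell (12 and 4 adjusted over the list alone). The collagen VI gene Col6a3 rose by 0.86 ± 0.13 and Col15a1 by 1.00 ± 0.17, while the cross-linking enzyme Lox fell by 0.93 ± 0.09 on the log2 scale. The list passed camera (limma adjusted p = 0.0157), but not with an estimated correlation (0.673), without control IgG replicate 1 (0.162) or without anti-FGFR1 replicate 5 (0.0522). Its mean per array did not separate the groups (exact permutation p = 0.134) and followed the macrophage mean (Pearson r = 0.941, permutation p = 4e-05, adjusted 0.00012; Spearman rho = 0.951, p = 6e-05, adjusted 0.00014; r = 0.892 without the 2 farthest arrays). These were 2 of 3 such relations computed, and no relation was detected between the macrophage and skeletal muscle means (r = -0.427, permutation p = 0.115, adjusted 0.115; rho = -0.301, p = 0.330, adjusted 0.330; r = -0.332 without the 2 farthest arrays). Of 10 fibroblast and preadipocyte markers, Lum, the matrix proteoglycan lumican, rose by 0.76 ± 0.10 and the receptor gene Pdgfra by 0.62 ± 0.09, while Pi16 fell by 0.50 ± 0.10 on the log2 scale, with its dimmer probe set at 0.06 (limma adjusted p = 0.759 for the list).

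Clock genes changed in both directions. Dbp (0.90 ± 0.15), Bhlhe40 (0.55 ± 0.09) and Nr1d2, which encodes the repressor REV-ERB beta (0.40 ± 0.07), rose, and so did Ciart (0.39). Nfil3 (-0.61), Cry1 (-0.41) and Arntl (-0.39), which encodes BMAL1, fell. These last 3 and Ciart are named after their values were seen. The other 10 of 17 clock genes did not pass, and the list had no common direction (limma adjusted p = 0.307 in camera). With the 3' to 5' covariate 3 rose and 0 of the falls passed limma, at log2 values of -0.48, -0.25 and -0.41.

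Of 16 glucocorticoid response genes, Lcn2 rose and 4 fell, among them the metallothionein gene Mt1 by 0.34 ± 0.05 and Angptl4, and the list did not pass (limma adjusted p = 0.111). The dimmer of the 2 probe sets of Mt1 differed by 0.04 and did not pass, and the call was lost with the mean of both (-0.15, limma adjusted p = 0.0658). Of 22 inflammatory cytokine and acute-phase genes, Lcn2 and the adhesion molecule Vcam1 (0.78 ± 0.11) rose, and Il1b (0.13) did not pass, nor did the list (limma adjusted p = 0.234). Of 17 interferon response genes only Ifit1 rose (0.29 ± 0.08), while Ifit3 (0.34) and Oas1a (0.21) did not pass. The call of Ifit1 was lost when any of 7 arrays was left out, and with the 3' to 5' covariate (0.29 ± 0.11, limma adjusted p = 0.177). The list did not pass camera (limma adjusted p = 0.0901), though it did without control IgG replicate 6 (0.0093), anti-FGFR1 replicate 5 (0.0210) or anti-FGFR1 replicate 6 (0.0139). Of 27 genes of the unfolded protein and amino acid response, the pseudokinase gene Trib3 (0.63 ± 0.12) and Sesn2 (0.21 ± 0.06) rose and Vldlr (-0.21 ± 0.06) fell. The list passed camera narrowly (limma adjusted p = 0.0478, and 0.573 with an estimated correlation), a call that leaving out any of 6 arrays ended. The calls of Sesn2 and Vldlr were lost when any of 5 and 8 arrays was left out. With the 3' to 5' covariate 4 members of the list rose and 0 fell. Sesn2 (limma adjusted p = 0.0577) and Vldlr (limma adjusted p = 0.310) lost their calls with it.

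Skeletal muscle markers, which can come with brown fat in dissection, varied widely. Their mean was 10.7 ± 0.87 in controls and 10.2 ± 1.67 after anti-FGFR1 (SD, n = 6 per group, exact permutation p = 0.608), and anti-FGFR1 replicate 5 stood apart at 6.88. Of the 20 markers 0 passed limma, and 0 had an unadjusted p under 0.05, with a median of -0.55, 1 of 20 above 0, and differences of -0.48 (Myoz1), -0.34 (Casq1) and -0.75 (Ckm). Without anti-FGFR1 replicate 5 these were -0.23, -0.18 and -0.098, and the mean of the list was 0.145 higher after anti-FGFR1 (exact permutation p = 0.773). Camera gave a limma adjusted p of 0.111 for this list, which passed without control IgG replicate 6 (0.00678), anti-FGFR1 replicate 2 (0.0142) or anti-FGFR1 replicate 6 (0.0203), and on ranks (0.0129), and turned direction without anti-FGFR1 replicate 5 (0.481). With an estimated correlation the adjusted p was 0.743. Of 11 nerve and Schwann cell markers, S100b (0.36 ± 0.05) and Npy (0.27 ± 0.08) rose and Mbp fell by 0.23 ± 0.05 on the log2 scale (limma adjusted p = 0.234 for the list). The call of Npy was lost when any of 10 arrays was left out, and with the 3' to 5' covariate (0.20 ± 0.10, limma adjusted p = 0.333). That of Mbp, with 2 of 8 probe sets passing, was lost with the 3' to 5' covariate (-0.21 ± 0.07, limma adjusted p = 0.128) and with the mean of its probe sets (-0.21, limma adjusted p = 0.233). Of 5 red blood cell markers, Alas2 fell by 0.41 ± 0.11 on the log2 scale, and Epb42 (0.10) and Slc4a1 (0.07, with 1 of 3 probe sets at -0.22) did not pass (limma adjusted p = 0.819 for the list). The call of Alas2 was lost when any of 6 arrays was left out, and with the 3' to 5' covariate (-0.34 ± 0.14, limma adjusted p = 0.241). Median, mean and test direction differed in sign for the circadian clock, glucocorticoid response, fibroblast, secreted factor and red blood cell lists, none of which passed camera.

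**Figure D2:**
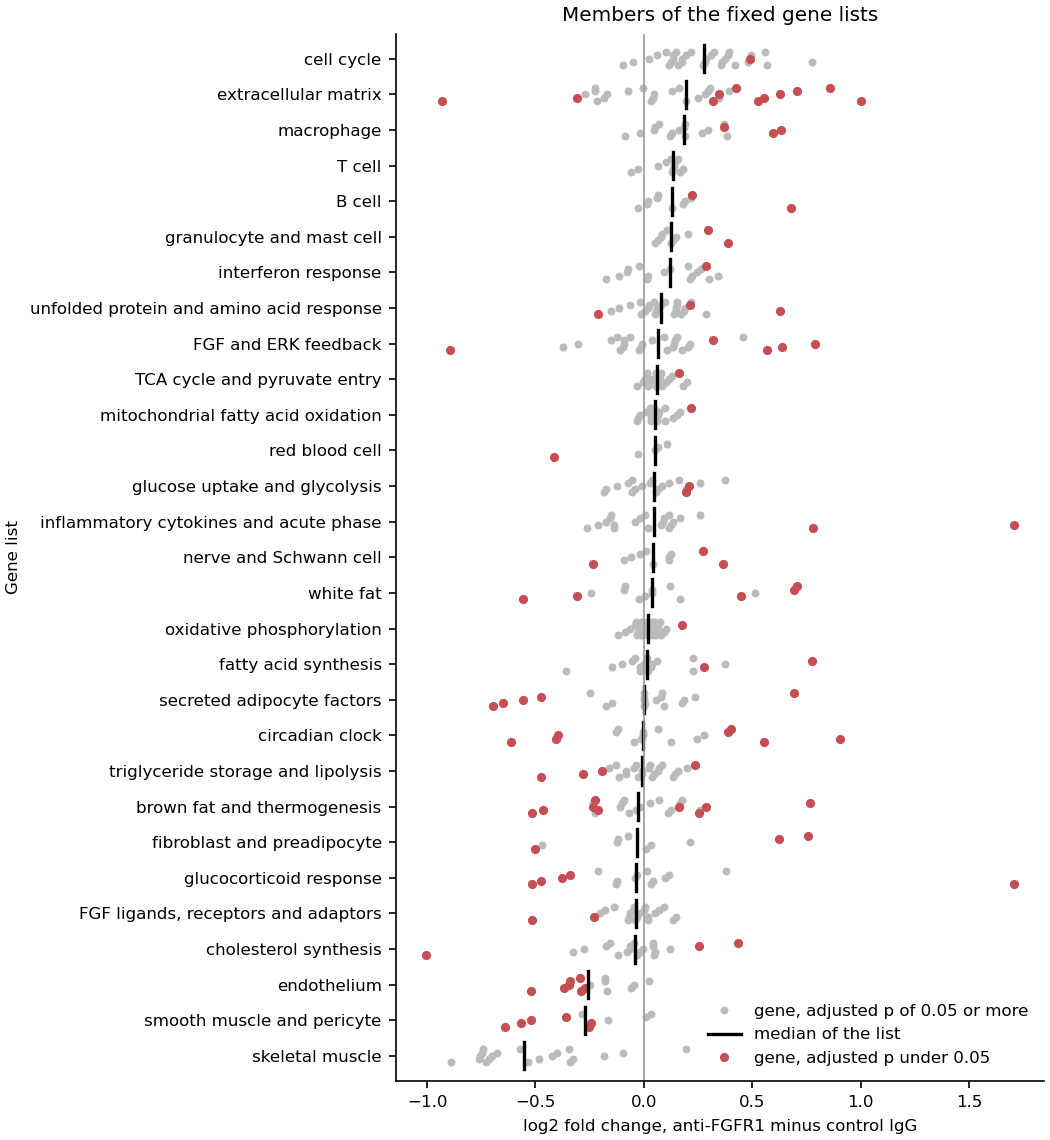
Log2 fold change (x axis, anti-FGFR1 minus control IgG) of each measured gene of the 29 lists, with 1 point per gene, red where the limma adjusted p was under 0.05, and a bar at the median of the list. Skeletal muscle lies farthest to the left with a median of -0.55, where 0 of 20 genes passed, then the vessel lists with medians of -0.26 and -0.27, and cell cycle lies to the right with a median of 0.28.

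**Figure D3:**
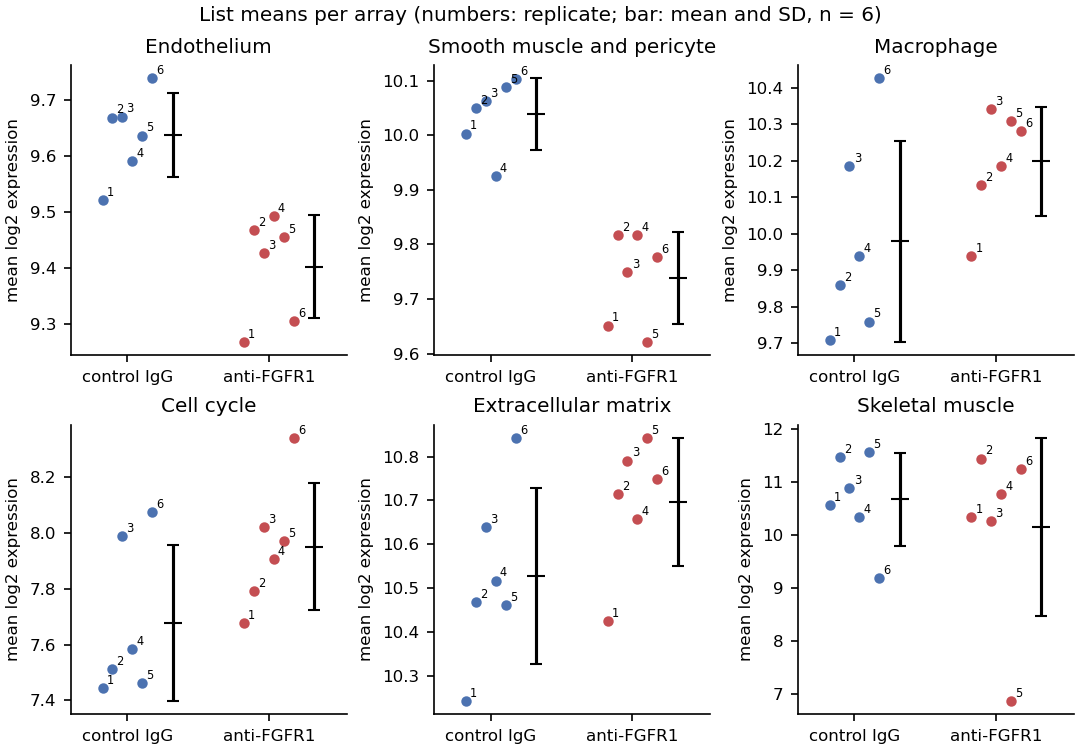
Mean log2 expression (y axis) of 6 lists on each array, with 1 point per array numbered by replicate, and the mean and SD of each group (n = 6). Endothelial and smooth muscle means do not overlap between the groups, whereas the macrophage, cell cycle and matrix means do, and anti-FGFR1 replicate 5 is lowest in skeletal muscle markers at 6.88.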

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

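The tests of a uniform loss of vessel cells, of macrophage content and of the hour of collection were chosen only after results they draw on were seen. The tests of regrouping, of skeletal muscle and of RNA quality were set out before.

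Regrouping the arrays bore on the count of changed genes as a whole. The real grouping of anti-FGFR1 against control IgG gave 1461 genes. Of 462 possible splits of the 12 arrays into 6 and 6, 100 were examined, the real one among them. Only the real split gave as many changed genes, and the highest of the others gave 76. Chance is thus an unlikely source of the count, though the remaining splits were not examined.

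Vessel markers were lower as a set. The 24 endothelial, smooth muscle and pericyte markers differed by -0.26 on the log2 scale, and by -0.259 (95% interval -0.358 to -0.161) with the skeletal muscle mean as a covariate, which argues against muscle carried over in dissection. With the 3' to 5' ratio as a covariate the difference was -0.225 (95% interval -0.340 to -0.110), an interval too wide to exclude the smaller fall set beforehand as a sign of this cause, so a difference in RNA quality cannot be told apart from the treatment, because the ratio itself differs between the groups. The spread over the markers, from Tagln (-0.64) to Mylk (0.03), was wider than under permuted labels (exact permutation p = 0.00866). This argues against an equal fall of the measured values, but cannot decide on a loss of vessel cells that lowers every marker alike. Probe sets respond unequally, as the 3 of Acta2 were at -0.57, -0.28 and -0.18, and markers that other cells also express could fall less. Kdr (0.02), Vwf (-0.05), Flt1 (-0.06) and Pdgfrb (0.0086) hardly differed, and these arrays do not show whether other cells express them. No test here separates lower expression within vessel cells from a loss of vessel cells, equal or unequal over their types.

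The cell cycle and matrix lists passed camera at the preset correlation but not with an estimated one (limma adjusted p = 0.573 and 0.673). Their means per array followed that of the macrophage markers and did not separate the groups (exact permutation p = 0.0974 and 0.134). The cell cycle difference passed that test without control IgG replicate 6 (0.352, exact permutation p = 0.0303), though the groups still overlapped. With the macrophage mean as a covariate, the cell cycle difference went from 0.27 to 0.0491 (95% interval -0.135 to 0.233) and the matrix difference from 0.17 to 0.00455 (95% interval -0.0883 to 0.0974). Differences between arrays that the macrophage mean tracks may thus account for both list shifts. The covariate cannot tell macrophage content from other differences that vary with it. Control IgG replicate 6, for example, was the highest control in the macrophage (10.4), cell cycle (8.07), matrix (10.8) and fibroblast (9.11) means. The macrophage mean was itself 0.22 higher after anti-FGFR1 (exact permutation p = 0.121, and 0.0173 without control IgG replicate 6), so the covariate may also remove a response to the treatment. Single matrix genes went beyond it: 6 members still rose with the covariate, among them Col15a1 (0.70) and Col6a3 (0.60), and 5 fell, among them Lox (-1.003). A change in matrix composition beyond what the macrophage mean tracks is a hypothesis that these arrays leave open.

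Some clock genes rose and others fell, and 10 of 17 did not pass. A contrast of 10 clock output genes, led by Dbp, minus 5 genes of the opposite arm, such as Arntl and Nfil3, was 0.522 higher after anti-FGFR1 (1.95 ± 0.12 against 1.43 ± 0.21, SD, n = 6 per group), but it was built after the values were seen, so it restates the pattern and does not test it, and Per1 (-0.13), Hlf (-0.05), Bhlhe41 (-0.02) and Tef (-0.0021) among the output genes were not higher. Groups collected at different hours could give such a contrast, and so could a response of the clock to the treatment or to the timing of meals under pair-feeding. The labels give no hour, so these cannot be told apart.

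Single arrays lay far from the other 5 of their group in 14 of 274 groups of 6 values, where chance gives about 1 in 20. The skeletal muscle mean of anti-FGFR1 replicate 5 was 6.88 against 10.3 to 11.4, and Ckm, muscle creatine kinase, was 7.19 there against 10.5 to 11.7. The granulocyte and mast cell mean of anti-FGFR1 replicate 2 was 7.29 against 7.11 to 7.16. The fibroblast and preadipocyte mean of control IgG replicate 6 was 9.11 against 8.80 to 8.84, and Oas1a, an antiviral gene, was 8.97 there against 8.38 to 8.55. Anti-FGFR1 replicate 6 lay far below the others in 3 genes, Sgk2 (9.13 against 9.46 to 9.60), Cpt2 (13.3 against 13.4 to 13.5) and Suclg2 (11.6 against 11.8). Ifit1 was 7.71 in anti-FGFR1 replicate 4 against 7.19 to 7.38. In control IgG replicate 1 the 3' to 5' ratio was 0.221 against 0.139 to 0.163, and Ms4a1 was 6.90 against 6.71 to 6.78. Among other controls, Fgf21 was 7.69 in replicate 5 against 7.21 to 7.38, Pou2af1 was 4.64 in replicate 2 against 4.78 to 4.86, and Npy was 7.09 in replicate 4 against 7.42 to 7.58.

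Probe sets without a single gene name carried signal too. Of 10092 such probe sets 221 changed (limma), 82 higher and 139 lower. The log2 fold changes of those that changed most were 1.00 and 0.89 among the rises, and -0.72 and -0.67 among the falls.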

How the results depend on the processing

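Leaving out the 2 arrays lowest in skeletal muscle markers and the fits with the macrophage mean as a covariate were chosen only after the data were seen. Under the alternatives, values of the named genes kept direction and side of the threshold in 2234 cases, lost the call in 156, gained it in 46 and changed sign in 12. Those that gained it under some alternative were Fgfr1, Kl, Ppargc1a, Pdk2, Suclg2, Echs1, Hk1, Pnpla3, Kif11, Prc1, Il1b, Oas1a, S100a9 and Ckm. Ckm did so with the skeletal muscle mean as a covariate (-0.25, limma adjusted p = 0.0274), a mean that includes Ckm itself. The 1461 changed genes (535 higher, 926 lower) became 688 (281 higher, 407 lower) with the 3' to 5' covariate; of 74 named genes that had passed, 51 passed with it. They became 614 (195 and 419) at an adjusted p under 0.01, 9 (5 and 4) with an absolute log2 fold change of at least 1, and 2398 with 1650 lower when all probe sets were tested. Leaving out 1 array gave 1043 to 1698 genes (364 to 585 higher, 664 to 1113 lower); the fewest came without control IgG replicate 3. It ended at least 1 call in 12 named genes, with adjusted p up to 0.105 (limma). Without the 2 arrays lowest in muscle markers 1016 genes passed, and 2115 with the macrophage covariate. The mean of all probe sets gave smaller folds, still called, for Adamts12 (0.64), Lox (-0.59), Vcam1 (0.40), Pdgfra (0.34), Pi16 (-0.22) and Ighm (0.17).

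Of 29 lists, 11 passed camera. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05), with fry 3, with the macrophage covariate 6, and leaving out 1 array 8 to 14, which can include lists outside the 11. The macrophage covariate is the mean of the macrophage list's own members, so it removes that list's shift by construction. In the exact permutation test, adjusted over the lists, the means per array of 5 lists passed. They were endothelium, smooth muscle and pericyte (adjusted p = 0.0314 each), TCA cycle and pyruvate entry, B cell, and granulocyte and mast cell (0.0377 each).

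Whether replicate numbers pair the samples was left unsettled. The correlation of deviations passed 0.1 in 3 of 6 pairs, replicates 1 (0.285), 2 (0.329) and 3 (0.218). These 3 of 6 controls correlated best with their own number, and replicates 4, 5 and 6 were at -0.0038, -0.29 and -0.12. A replicate block gave 1337 genes, 535 higher and 802 lower. It ended 7 calls of named genes (Uqcrc2, Pdhb, Nsdhl, Sesn2, Ifit1, Ighm and Alas2) and gained 3 (Kif11, Prc1 and Pdk2).

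The results that changed sign had not passed. Egr1 was 0.0082 after another quantile normalization, 0.40 with the 3' to 5' covariate, 0.051 without the 2 arrays lowest in muscle markers, and -0.30 to 0.23 leaving out 1 array. With the mean of all probe sets Klb was 0.055, Dio2 -0.089 and Slc4a1 -0.036, and with the 3' to 5' covariate Slc4a1 was -0.047. Lists turned as follows, by adjusted p (limma): fibroblast, 0.885 on ranks, 0.981 with the replicate block, 0.890 with the macrophage covariate; triglyceride storage, 0.819 without shared genes, 0.874 among bright genes, 0.824 with the 3' to 5' covariate; brown fat, 0.874 among bright genes, 0.609 with that covariate; cholesterol synthesis, 0.8288 with it; red blood cell, 0.814 with array weights; FGF and ERK feedback and skeletal muscle, 0.969 each with the macrophage covariate. Leaving out 1 array gave adjusted p of 0.604 to 0.996 (red blood cell), 0.343 to 0.969 (brown fat), 0.450 to 0.922 (fibroblast), 0.00678 to 0.481 (skeletal muscle) and 0.4934 to 0.969 (triglyceride storage), and a skeletal muscle mean difference of -0.81 to 0.15, positive only without anti-FGFR1 replicate 5. Stricter thresholds lower counts by construction; otherwise the cause was not tested. Near the top of the array's range, as for Ucp1, Cidea and Adipoq, changes may be compressed, which was not measured. The lists of TCA cycle, fatty acid oxidation and oxidative phosphorylation were also bright, with control means of 13.25, 13.28 and 13.38.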

Other observations

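The gene lists here were chosen only after the results were seen, so their tests describe these arrays and give no independent evidence. Enzymes that break down the branched-chain amino acids were higher after anti-FGFR1: of 24 measured genes, 11 rose and 0 fell (limma), and 20 were above 0, with a median of 0.18. Dbt, the core subunit of the branched-chain ketoacid dehydrogenase, rose by 0.53 ± 0.05, and the mitochondrial aminotransferase gene Bcat2 by 0.38 ± 0.05. Mcee and Hibch, further down the pathway, rose by 0.38 ± 0.07 and 0.32 ± 0.06 (SE, limma, n = 6 per group). With the 3' to 5' ratio as a covariate 4 of the 24 rose, and with the skeletal muscle mean 11 did. The list passed camera at the preset correlation (limma adjusted p = 4.6e-09) but not with an estimated one (adjusted p = 0.0991).

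Genes of antigen presentation by MHC class II were also higher: 4 of 9 rose, H2-Aa by 0.69 ± 0.15, H2-Eb1 by 0.62 ± 0.11, H2-Ab1 by 0.59 ± 0.15 and the invariant chain gene Cd74 by 0.51 ± 0.12 (SE, limma), while 1 passed with the 3' to 5' covariate. Macrophages and B cells express these genes, and the means of their markers were 0.22 (exact permutation p = 0.121) and 0.16 (exact permutation p = 0.0065) higher. In the IGF axis, 3 of 10 genes fell and 0 rose (limma): the IGF-binding protein genes Igfbp5 (-0.60 ± 0.06), Igfbp3 (-0.58 ± 0.07) and Igfbp6 (-0.42 ± 0.08), with 2 called under that covariate. The other probe set of Igfbp5 was at 0.03. Of 24 Wnt pathway and target genes, 13 were above 0, with a median of 0.01, and the list did not pass camera at the preset correlation (limma adjusted p = 0.127). In it 5 fell and 0 rose (limma), namely Ccnd1, Sfrp2 (-0.80 ± 0.22), Axin2 (-0.53 ± 0.09), Wnt11 (-0.47 ± 0.09) and Fzd8 (-0.29 ± 0.07, with its dimmer probe set at 0.01), with 4 called under that covariate. The MHC class II and IGF axis lists passed camera at the preset correlation (limma adjusted p = 1.2e-05 and 0.00055). With an estimated correlation none of these 3 lists passed, at limma adjusted p values of 0.0592 for MHC class II and for the IGF axis, and 0.150 for Wnt.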
